A study of Homo sapiens with 8 samples.

How the data were processed

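RNA of CHP-134 cells was labelled with Cy3 from 150 ng per sample together with Agilent's spike-in controls and hybridised to SurePrint G3 Human 8x60K V2 arrays, per the labels' protocols. The series holds 2 RNA samples per group and 2 technical arrays per RNA sample, and the groups and sample numbers were taken from the sample titles. The deposited file of each array is the output of Agilent Feature Extraction 11.0.1.1, per the file headers. Its spot values are an intensity on a linear scale, background-subtracted by the scanner software and not normalized between arrays, per the file headers. The authors also deposited a table of their comparison, with a log2 fold change of MYCNcra over NC and a p-value and adjusted p-value for each probe; it was made with limma, per the submitters' processing notes, and its background correction and normalization between arrays are not given in the sources used here. The depth of an array is its signal over background, and for each RNA sample 2 arrays set the precision.

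All arrays were read spot by spot. Spots flagged as outliers were left out, saturated spots were kept, and spots of a probe were averaged. The processed signal was taken as log2 and shifted by each array's 75th percentile over non-control probes. A probe was kept if it was well above background on at least 4 of the 8 arrays, which left 21990 of 50599 probes. Gene symbols came from RefSeq accessions matched without versions to a gene table of the GRCh38.p14 assembly for 29033 probes, and from the symbols in the deposited table, updated through synonyms, for 8678; 12888 probes stayed without a name. The file headers name the hg19 build, so no coordinates are given and the gene table served only for names and neighbours. The brightest of a gene's probes stood for the gene, and 14409 genes were tested. Of 3842 genes with several probes, 3 had probes called in opposite directions. Where every array of a group was below background, a change is given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Named genes with 1 to 3 of a group's 4 arrays above background have fitted values, given in the text beside the value with the arrays raised in the same way where the change passed.

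Technical arrays of an RNA sample were averaged, and MYCNcra was compared with NC by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 3.78 prior degrees of freedom. An exact permutation test of 2 RNA samples against 2 cannot give a two-sided p under 0.333, so single values of arrays were not tested further. Gene lists of at least 5 measured genes (28 of 32) were compared with all other genes by camera with a correlation of 0.01. They were compared again with an estimated correlation and with fry. With an estimated correlation camera's test rests on the 2 residual degrees of freedom, so few lists could pass after adjustment. A failure there does not decide whether a list shifted. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. The rule took MYCN, the 12 largest rises and 12 largest falls among called genes with no overlap between the RNA samples of both groups and an established symbol, the 4 members with the smallest p of each list that passed, and up to 2 of each other list; a gene that the rule names but the text does not is not reported here. The 2 slides each held both groups, with the first technical arrays on one and the second on the other, so the slide was fitted as a block and each slide was also analysed alone. For the slide, 17.3% of genes had an unadjusted p under 0.05 by an F test, where chance gives 5%. None passed after adjustment, but few residual degrees of freedom were left, so an effect of the slide is not excluded.

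Alternatives were normexp background correction with an offset of 50, quantile, median and spike-in scaling, no filter and a filter on all 8 arrays, the mean of a gene's probes, all arrays as independent or with the RNA sample as a random block, each technical array alone, eBayes with trend and robust settings, the sample number as a block, the slide as a block, and each RNA sample left out. Values without the second array of the second MYCNcra sample, and values with no scaling between arrays, either of the processed signal in the same fit or of normexp values (offset 16) with 8 arrays as independent, were added after the data were seen. The normexp alternative used the median spot signal, since the files used here hold no mean signal. The spike-in scaling used the 7 of 10 spike-in probes that were above background on all arrays. Simulated data for this comparison took the means and technical spread of the 14409 real genes, with the difference between slides left in that spread. Each RNA sample also drew noise of its own, scaled to that spread, and each array a common shift. The fit was tested on these data, with 200 genes changed by known folds in 20 runs. It recovered 82.6% of 50 genes changed 4-fold, 32.8% of those changed 2-fold, 0.7% of those changed 1.5-fold and 0% of those changed 1.25-fold, and 2.93% of its calls were false. A planted list was found in 20 of 20 runs and an unchanged list in 0. A run made 59.8 calls on average, against 2224 in the real fit, so the recovery rates belong to the simulated setting only. Noise was drawn independently for each gene, so the list result does not test camera on correlated genes.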

Results

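Gene expression was measured in CHP-134, an established human neuroblastoma cell line that carries an amplified MYCN gene. The cells had received either a CRISPR/Cas9 construct aimed at MYCN, here called MYCNcra, or a CRISPR/Cas9 negative control, here called NC; whether the control construct breaks DNA is not given in the sources used here. RNA was taken 6 h after transfection. Each group held 2 RNA samples, and each RNA sample was hybridised to 2 one-colour Agilent arrays, which gave 8 arrays. Between 20312 and 23149 of the 50599 non-control probes lay well above background on an array, and the 75th percentile of the signal lay between 234 and 324 on the MYCNcra arrays and between 321 and 399 on the NC arrays. Across the 14409 genes tested, arrays of the same group correlated with r between 0.993 and 0.996, and arrays of different groups with r between 0.981 and 0.986 (Pearson, across genes, which are not independent replicates). The median SD between the RNA samples of a group, each the mean of 2 arrays, was 0.07 (log2) in MYCNcra and 0.07 in NC, and the median SD between single technical arrays was 0.10. The SD between technical arrays still holds the difference between the slides. With the slide fitted, the F statistic of RNA samples within groups over technical arrays had a median of 1.31, where chance gives 0.881. By this test 6.82% of genes had an unadjusted p under 0.05, where chance gives 5%, and none passed after adjustment. The labels do not say whether the RNA samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

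The targeted transcript was examined first. MYCN had a mean log2 level over the array's 75th percentile of 7.02 ± 0.05 in MYCNcra and 7.18 ± 0.03 in NC (SD, n = 2 RNA samples each). The difference of -0.16 ± 0.08 (SE, log2) did not pass the limma test (adjusted p = 0.225), although both MYCNcra RNA samples lay below both NC samples. It was -0.24 on the first slide and -0.08 on the second. Only 1 probe for MYCN passed the filter, and its place relative to the DNA break is not given in the sources used here, so this level is no measure of how many gene copies were broken. The direction was negative under every setting tried, but the size changed with the scaling between arrays and with the background correction, as reported with the deposited comparison.

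**Figure D1:**
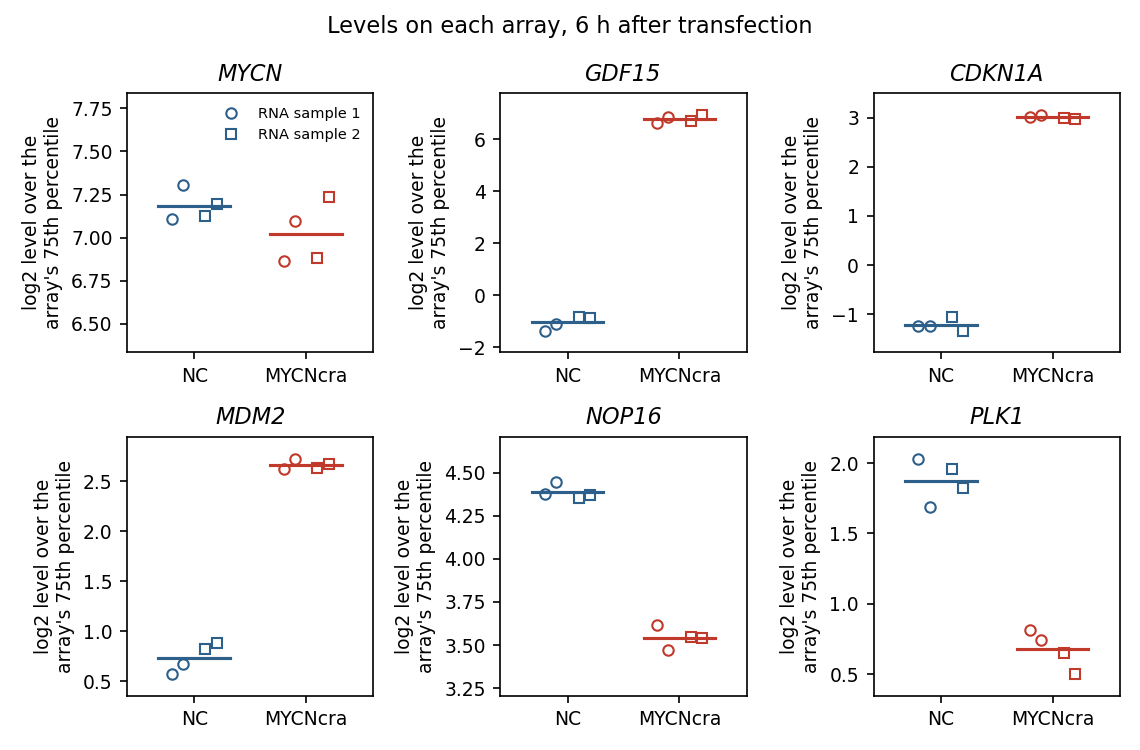
Levels of 6 genes on each of the 8 arrays, as log2 signal over the array's 75th percentile (y axis, a separate range for each gene); circles and squares are the 2 RNA samples of each group, symbols of a kind are technical arrays, and horizontal lines are group means. MYCN lies at 7.18 in NC and 7.02 in MYCNcra, while GDF15 and CDKN1A differ by 7.82 and 4.23 with no overlap between groups.

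The question of which transcripts differed between the groups was then addressed across all genes. In MYCNcra 1182 genes were higher and 1042 lower than in NC (limma, adjusted p under 0.05). Rises were much larger than falls: with genes dim on all arrays of a group taken at their lower bound, 296 genes rose by 2-fold or more and 87 by 4-fold or more, against 45 and 0 that fell by as much (297, 112, 48 and 1 with fitted folds). In 63.0% of all tested genes both RNA samples of one group lay on the same side of both samples of the other, where chance gives 33.3%. Every called gene was separated in this way, but with 2 RNA samples per group an overlapping gene could not pass the test. The separation of the called genes is therefore no further evidence. With the slide as a block 1674 genes were higher and 1790 lower; the first slide alone gave 703 and 494, and the second 387 and 136. Leaving out 1 RNA sample gave 867 and 606 without the first MYCNcra sample, 976 and 763 without the second, 666 and 316 without the first NC sample and 618 and 318 without the second. The split between higher and lower calls depended on the scaling. Shifting each array by its median gave 739 higher and 5302 lower genes, with the median gene at -0.23, and scaling to the spike-in controls gave 249 and 909, with the median gene at -0.36. Quantile normalization gave 1048 and 1071, and the median gene lay at -0.01 in the values reported here. Under the quantile, median and spike-in scalings no called gene was called in the opposite direction. Under spike-in scaling, however, only 972 of the called genes kept their call, and 46 took the other sign without passing.

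The largest fitted rise was that of GDF15, at 227-fold (log2 difference 7.82 ± 0.14 SE, n = 2 per group, limma adjusted p = 1.55e-05). GDF15 encodes a stress-induced secreted growth factor and is a known p53 target. It was well above background on all arrays of both groups. Most of the other large rises came from probes not well above background on any NC array, for which only a lower bound can be given. The 12 genes were ranked by fitted difference. Some bounds are therefore smaller than rises measured on every array, such as those of ACTA2 (23.6-fold) and CDKN1A (18.7-fold). CRYBG2 was at least 29.97-fold higher, TMT1A at least 37.4-fold, MYBPHL at least 23.6-fold, and TREM2, a receptor of the immunoglobulin superfamily, at least 22.2-fold. The long non-coding RNA LINC01054 was at least 21.5-fold higher, the epidermal transcription factor ZNF750 at least 18.6-fold, and CFAP251 at least 17.3-fold. EDN2, an endothelin peptide gene, was at least 8.94-fold higher and PURPL, a long non-coding RNA known to be induced by p53, at least 8.52-fold. NECTIN4, a cell adhesion gene, and SCN4B, a sodium channel subunit, were each above background on only 1 NC array, and their fitted differences of 6.17 and 4.93 (log2) became 5.10 and 4.05 with the NC arrays raised to the lowest level well above background. All 12 genes passed the limma test, with adjusted p between 1.12e-05 and 0.00174.

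Ranked by fitted difference, the 12 largest falls were smaller than the rises and came mostly from dimmer probes. Values below background entered this ranking. Some of the bounds and raised values below are therefore smaller than falls measured on every array, such as that of PLK1 (2.30-fold). The small nucleolar RNA SNORD1A was at least 2.63-fold lower in MYCNcra, the scavenger receptor SCARA5 at least 2.64-fold, the neuroblastoma-associated LIM-only gene LMO3 at least 1.79-fold, and SLC2A4, the insulin-responsive glucose transporter, at least 1.44-fold; none of these was well above background on a MYCNcra array. SHISA3 fell 2.94-fold, from 0.11 to -1.45 (log2 level), INHBE, an inhibin beta subunit, 2.67-fold, and EVPLL 2.52-fold, all 3 measured on every array. CYP27B1, the enzyme that makes active vitamin D, fell 2.87-fold, the cyclin gene CCNA1 2.81-fold, the circadian repressor CIART 2.67-fold, and PDZRN3 2.47-fold, and the amine oxidase AOC3 fell by 1.32 on the log2 scale, with 1, 2, 3, 3 and 1 of the 4 MYCNcra arrays above background. With those arrays raised to the lowest level well above background, CYP27B1 was 1.94-fold, CCNA1 1.86-fold, CIART 2.66-fold, PDZRN3 2.47-fold and AOC3 2.25-fold lower. Adjusted p for the 12 falls lay between 0.000786 and 0.0335.

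Targets of p53, the transcription factor that responds to DNA damage, moved most as a group. All 35 measured p53 targets rose, also when adjusted over the list alone, with a median log2 difference of 1.91, and 16 of them rose by 4-fold or more. CDKN1A, the cell cycle inhibitor p21, rose 18.7-fold (4.23 ± 0.08 SE), DRAM1, a regulator of autophagy, 15.5-fold (3.95 ± 0.08), and FDXR, a mitochondrial reductase, 8.53-fold (3.09 ± 0.08). MDM2, which encodes the ligase that degrades p53, rose 3.81-fold (1.93 ± 0.10), and the smallest rise was that of AEN at 0.59 ± 0.08. The median was 1.94 in the first MYCNcra RNA sample and 1.88 in the second, relative to the NC mean, and 1.94 and 1.87 on the 2 slides. The list shifted against the other genes with camera's preset correlation (adjusted p = 1.08e-36). With an estimated correlation it did not pass (p = 0.0171, adjusted p = 0.478), while fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00486. The test with an estimated correlation has only 2 degrees of freedom, here and for the lists below, so its failures do not decide. The estimated correlations also lay above the preset 0.01. They were 0.09 for p53 targets, 0.16 for MYC targets, 0.23 for mitotic, 0.17 for immediate early and 0.63 for ribosomal protein genes. If members move together that much, the p-values with the preset correlation are too small, most of all for ribosomal protein genes.

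**Figure D2:**
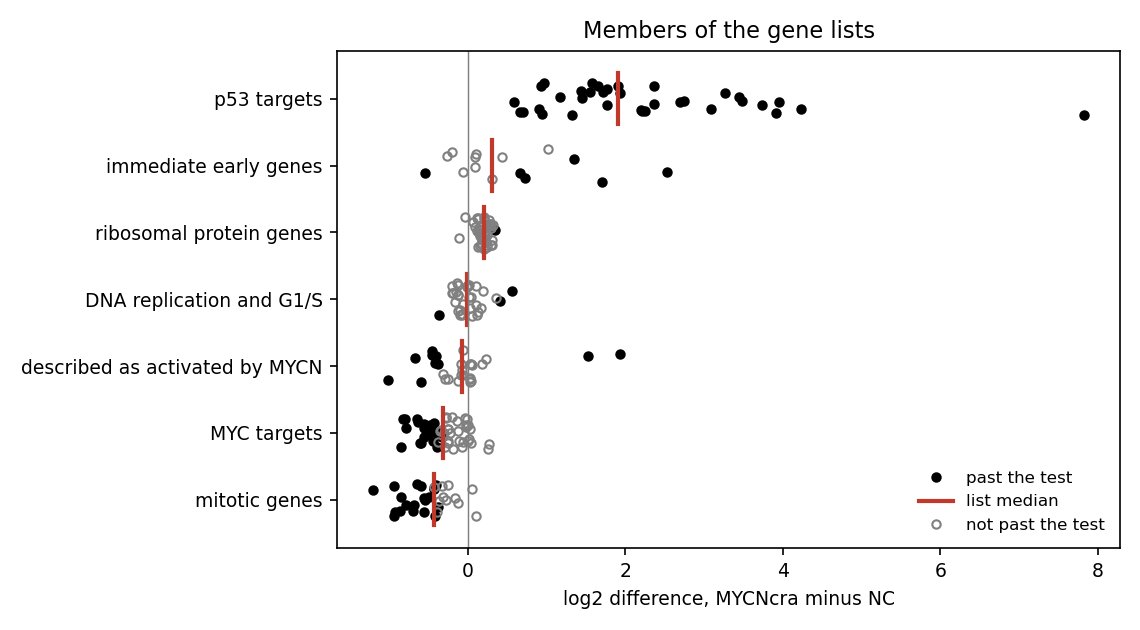
Log2 difference of MYCNcra minus NC (x axis) for each measured member of 7 gene lists; filled points passed the limma test at adjusted p under 0.05, open points did not, and red bars are list medians. All 35 p53 targets lie to the right of 0 with a median of 1.91, the medians of MYC targets and mitotic genes lie at -0.31 and -0.43, and that of DNA replication genes at -0.01; the ribosomal median of 0.21 turned negative under median and spike-in scaling, as did the median of all genes (-0.23 and -0.36).

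MYC targets and mitotic genes were lower in MYCNcra. Of 54 measured nucleolar and growth genes described as MYC targets, 24 fell and none rose; adjusted over the list alone 33 fell and 1 rose. NOP16, a ribosome assembly factor, fell 1.79-fold (log2 difference -0.84 ± 0.08 SE), the pseudouridine synthase PUS1 1.73-fold, the coactivator PPRC1 1.72-fold and the folate transporter SLC19A1 1.55-fold. The list's median was -0.31, and -0.29 and -0.33 on the 2 slides (camera adjusted p = 1.63e-09, but adjusted p = 0.694 with an estimated correlation). Of 31 mitotic genes, 20 fell and none rose, and 26 fell when adjusted over the list alone. PLK1, a kinase needed for entry into mitosis, fell 2.30-fold (-1.20 ± 0.10), and CDC20, AURKA and CCNB1 had differences of -0.94, -0.93 and -0.92, which all passed. Their median was -0.43, with -0.46 and -0.45 on the 2 slides (camera adjusted p = 6.78e-12, but adjusted p = 0.694 with an estimated correlation). For MYC targets and mitotic genes fry gave adjusted p of 0.0345 and 0.0333. The DNA replication and G1/S genes did not shift as a list: of 33 measured members 2 rose and 1 fell, 2 and 0 when adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.912). PCNA, the sliding clamp of DNA polymerase, rose by 0.56 ± 0.09 and CCND1, cyclin D1, by 0.42 ± 0.08.

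Immediate early genes and ribosomal protein genes also shifted with camera's preset correlation, less firmly. Of 15 measured immediate early genes 5 rose and 1 fell, also when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0315, but adjusted p = 0.694 with an estimated correlation). ARC, a neuronal activity gene, rose 5.78-fold, DUSP6, a phosphatase of the MAP kinase pathway, 3.25-fold, ATF3, a stress-induced transcription factor, 2.55-fold and IER5 1.59-fold. The slides alone gave medians of 0.34 and 0.24, and the median turned to -0.05 under spike-in scaling, where the median of all genes lay at -0.36 and the list still passed camera's test against the other genes (adjusted p = 0.000417). The call ended without the second MYCNcra sample (adjusted p = 0.0661) and without the first NC sample (median 0.11, adjusted p = 0.119). The 42 ribosomal protein genes had a median of 0.21, with 0.14 and 0.29 on the 2 slides (camera adjusted p = 9.31e-06; adjusted p = 0.816 with an estimated correlation), and this turned to -0.02 under median and -0.15 under spike-in scaling, which moved the median of all genes to -0.23 and -0.36. Against the other genes the list still passed camera's test under median scaling (adjusted p = 0.00102) but not under spike-in scaling (adjusted p = 0.180). After quantile normalization its median was 0.02 and did not pass (adjusted p = 0.379), and random lists of genes matched on mean signal had a median of 0.10 and reached 0.20, so part of the value goes with signal level. RPL19 was the only member to rise (0.35 ± 0.09, adjusted p = 0.0490; -0.0042 under spike-in scaling), none did when adjusted over the list alone, and RPS19, RPS27 and RPLP2 had differences of 0.32, 0.31 and 0.32.

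The remaining lists that concern MYCN did not pass camera's test (adjusted p of 0.158 or more), and 1 of them, the genes described as repressed by MYCN, passed fry (adjusted p = 0.00486). Among 28 genes described as activated by MYCN in neuroblastoma, 2 rose and 8 fell, 2 and 9 when adjusted over the list alone; those that rose were MDM2, also a p53 target, and GLDC, a glycine-cleaving enzyme (2.88-fold). Of 9 measured genes described as repressed by MYCN, 3 rose and 0 fell, or 4 and 1 when adjusted over the list alone, among them CDKN1A and NDRG1 (1.45-fold); their median of 0.33 turned to -0.02 under spike-in scaling, where the median of all genes lay at -0.36 and the list passed camera's test (adjusted p = 0.00301). In the MYC, MAX and MXD network 2 rose and 3 fell of 13, and 3 and 3 when adjusted over the list alone; MXD1, a MAX partner that opposes MYC, rose 2.03-fold and MLXIPL 1.54-fold. Of 10 measured genes near MYCN on 2p24, CYRIA rose 1.57-fold and TRIB2 fell 1.41-fold, in both adjustments, and the list's median was 0.03.

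Lists of stress and signalling genes did not pass camera's test (adjusted p of 0.158 or more), and single members changed. Counts in both directions follow, with those adjusted over the list alone in brackets. Of 24 homologous recombination and Fanconi genes 0 rose and 2 fell (0 and 1), CHEK2 by 1.37-fold and ATM by 1.28-fold. Of 18 apoptosis regulators 3 rose and 1 fell (3 and 1), with APAF1, a core part of the apoptosome, up 2.46-fold and BMF 2.01-fold. Of 15 interferon-stimulated genes 2 rose and 2 fell (2 and 3), HERC5 rising by 1.32 (log2) and ISG20 falling 1.69-fold. Of 7 NF-kB targets 2 rose and 0 fell (3 and 0), RELB by 2.90-fold and IER3 by 1.62-fold. HSPA4L rose 3.62-fold as the only called one of 19 heat shock genes (1 and 0), and STIP1 had a difference of -0.26. Of 28 integrated stress response genes 4 rose and 7 fell (4 and 7). NUPR1 was at least 4.14-fold higher and ATF3 rose as above, while those that fell included CHAC1 (1.92-fold) and DDIT3 (1.88-fold). Of 18 unfolded protein response genes 0 rose and 1 fell (0 and 0), ERO1A by 1.29-fold, and EDEM1 had a difference of 0.40. Of 23 hypoxia and glycolysis genes 1 rose and 5 fell (3 and 5), HK2 falling 1.55-fold and NDRG1 rising. Of 22 cholesterol synthesis genes 3 rose and 0 fell (3 and 0), among them STARD4 by 1.83-fold. Of 15 oxidative stress genes 0 rose and 1 fell (0 and 1), SLC7A11 by 1.47-fold, and FTH1 had a difference of 0.31. Of 8 metallothionein and zinc genes 1 rose and 0 fell (1 and 0), SLC30A1 by 1.30-fold, and MT2A had a difference of 0.32.

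Growth, identity and cell type lists likewise did not pass (camera adjusted p of 0.0602 or more). Of 22 replication-dependent histone genes 0 rose and 3 fell (0 and 1), H4C3 by 1.44-fold and H1-5 by 1.28-fold. Of 17 small nucleolar RNA host genes 0 rose and 6 fell (1 and 8), SNHG17 by 1.58-fold and SNHG15 by 1.43-fold. None of 26 oxidative phosphorylation genes passed in either adjustment; COX6C and COX5A had differences of 0.30 and 0.29. Of 23 adrenergic neuroblastoma identity genes 0 rose and 2 fell (0 and 1), LMO1 by 1.48-fold and INSM1 by 1.28-fold. Of 10 mesenchymal identity genes 1 rose and 2 fell (4 and 2), PRRX1 by 2.04-fold and CCN1 by 1.52-fold. Of 24 neuronal differentiation genes 1 rose and 1 fell (1 and 1), NEFL rising 1.48-fold and NTRK3 falling 1.33-fold. Among markers of other cell types, 2 of 6 fibroblast genes rose and 1 fell (2 and 2), with the smooth muscle actin gene ACTA2 up 23.6-fold and COL1A1 1.45-fold, but the median was -0.18. Fewer than 5 markers were measured for the other cell types, which were not tested as lists. Of 2 Schwann cell markers 1 rose and 0 fell (1 and 1), FOXD3 by 2.39-fold (above background on 1 of 4 NC arrays, and 1.80-fold with these raised to the lowest level well above background), and PMP22 had a difference of -0.40. Of 3 immune markers 0 rose and 1 fell (1 and 1), CD14 by 2.19-fold, and CD68 had a difference of 0.24. Neither of the endothelial markers EGFL7 and CDH5 passed, and of 4 epithelial markers 1 rose and 0 fell (1 and 0), CLDN4 by 2.01-fold, while EPCAM had a difference of 0.31. Under fry 11 lists passed, among them 7 that camera did not call: the MYCN-repressed, homologous recombination, NF-kB, integrated stress response, hypoxia, host gene and neuronal lists.

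These values were set beside the authors' deposited table of the same comparison. Across 21983 probes the log2 differences of the authors' deposited table correlated with those reported here with r = 0.913 (Pearson, across probes), and 1455 probes were called in both with the same sign and 0 with opposite signs. The sign was shared by 61.5% of these probes. Over all its probes, the authors' deposited table called 546 higher and 7116 lower in MYCNcra. For MYCN the authors' deposited table gives a log2 fold change of -0.56 with an adjusted p of 0.00254. The t and p of that table's first row imply 13.4 degrees of freedom, against 2 residual and 3.78 prior here. The authors' fit may thus have counted technical arrays as separate samples. Its p-values and counts of calls are therefore not on the same footing as those reported here. Here MYCN passed the test after a median shift (-0.39, adjusted p = 0.0159) but not after spike-in scaling (-0.52, adjusted p = 0.199); both scalings shift all genes of an array alike, so the distance of MYCN from the median gene stayed at -0.16. That distance was -0.29 after quantile normalization, where MYCN did not pass (-0.31, adjusted p = 0.0723), and -0.28 with normexp background correction, where it passed (-0.26, adjusted p = 0.0197).

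**Figure D3:**
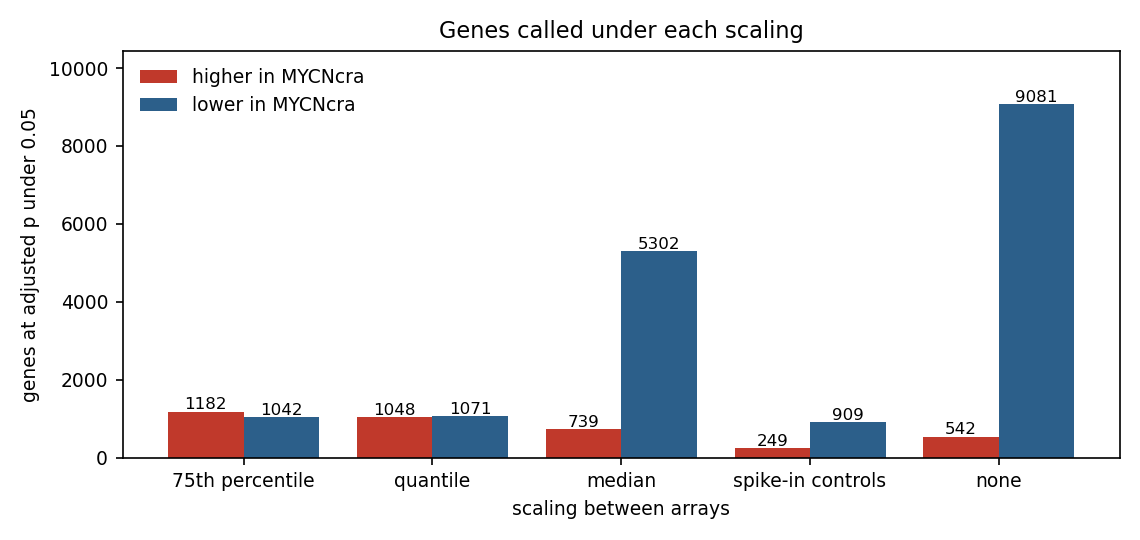
Number of genes at adjusted p under 0.05 (y axis) that were higher (red) or lower (blue) in MYCNcra under each way of scaling the arrays (x axis), with the same background correction, 2 RNA samples per group and the same limma fit throughout. The split runs from 1182 higher and 1042 lower with the 75th percentile to 542 and 9081 with no scaling.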

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

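All tests in this part were chosen after the results were seen. No array stood apart from the other 3 of its group in any of 28 comparisons of array measures, MYCN levels and list means; the arrays of a group share RNA, so they are not independent.

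Signal was found in probes that the gene comparisons did not use. Of 2432 tested probes without a gene name, 164 were higher in MYCNcra than in NC and 90 were lower. The strongest, A_21_P0002371, was well above background on 4 of 4 MYCNcra arrays and 0 of 4 NC arrays and was at least 14.9-fold higher in MYCNcra.

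The first pattern weighed is the excess of lower calls in the authors' deposited table, 7116 against 546. Log2 differences computed without any scaling between arrays (normexp with an offset of 16) correlated with those of the authors' deposited table with r = 0.999784 over 50599 probes and gave -0.56 for MYCN. This was the closest of 7 settings tried, so the choice of setting followed the data. Equalising the array medians came as close (r = 0.999777), quantile normalization gave r = 0.813, and none returned the counts of the authors' deposited table: no scaling gave 457 higher and 4910 lower probes, equal medians 522 and 6244, and no scaling with an offset of 50 gave 476 and 6398. Whether the arrays were scaled by their medians is thus left open. The fits behind these counts took each technical array as a separate sample, with 15.4, 15.1 and 10.2 total degrees of freedom in that order. Their counts are therefore not on the same footing as those from averaged technical arrays. Both of the closest settings left the 75th percentile lower in MYCNcra (-0.29 for each), since their array medians lay near background and hardly differed, whereas quantile normalization brought it to 0.01. A candidate explanation is that this difference in the brightness of bright probes was left in the values of the authors' deposited table. In the processed signal the 75th percentile differed by -0.37 ± 0.04 (log2, SE from 2 RNA samples per group). Whether that lower brightness came from labelling or from the RNA cannot be told apart: the spike-in signal differed by -0.01 ± 0.27, and the 75th percentile over the spike-in signal by -0.36 ± 0.23, with spreads between RNA samples too wide to decide.

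The second pattern is the fall of MYC targets and mitotic genes while MYCN itself did not pass the test. A bias with signal level is argued against, since 10000 random lists matched on mean signal had medians no lower than -0.13 for MYC targets (observed -0.31) and -0.22 for mitotic genes (observed -0.43). A single slide or RNA sample is argued against as well, since the median closest to 0 of either list over both slides and with each RNA sample left out was -0.28. Loss of MYCN product and a response to the DNA break itself both stay open. The genes described as activated by MYCN did not pass as a list (camera adjusted p = 0.158, fry adjusted p = 0.0601). This does not decide, since 8 members fell and the 2 that rose include the p53 target MDM2. Whether the NC construct breaks DNA elsewhere in the genome is not given in the sources used here. The difference between the groups, that of the p53 targets included, could thus hold a response to a break.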

How the results depend on the processing

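Both alternatives with no scaling between arrays and the one without the second array of the second MYCNcra sample were chosen after seeing the data; the others were planned. The p53, MYC target and mitotic lists kept their direction under every alternative run and passed under each of them except camera with an estimated correlation, where no list passed (0 of 28; adjusted p = 0.478 for p53 targets with a median of 1.91, and 0.694 for MYC targets at -0.31, mitotic genes at -0.43 and immediate early genes at 0.31, and 0.816 for ribosomal genes at 0.21). The test with an estimated correlation has only 2 degrees of freedom, so its failure alone does not decide against a list. The estimated correlations of these lists, up to 0.63 for ribosomal genes, also lay above the preset 0.01. The p-values with the preset correlation may therefore be too small. With fry 11 lists passed, and ribosomal genes did not (adjusted p = 0.209).

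Normexp background correction gave 2585 higher and 2110 lower genes, 9 called lists and a MYCN difference of -0.26 (adjusted p = 0.0197). CDH5, measured near background, reversed to 0.24 and passed there (limma adjusted p = 0.0284). It was above background on only 1 of 4 MYCNcra arrays. A median shift gave 739 higher and 5302 lower genes, MYCN at -0.39 (adjusted p = 0.0159) and ribosomal genes at -0.022, which still passed camera's test (adjusted p = 0.00102). Spike-in scaling gave 249 higher genes, immediate early genes at -0.047 (still passing camera's test against other genes, adjusted p = 0.000417), ribosomal genes at -0.15 (not passing, adjusted p = 0.180), genes described as repressed by MYCN at -0.023 (a call gained, adjusted p = 0.00301) and RPL19 at -0.0042. With no scaling there were 542 higher and 9081 lower genes, MYCN at -0.53 (adjusted p = 0.0045), immediate early genes at -0.059 (adjusted p = 6.9e-05), ribosomal genes at -0.16 (adjusted p = 0.0406), MYCN-repressed genes at -0.035 (adjusted p = 0.0406) and RPL19 at -0.016. Changing 3 choices together, normexp values (offset 16), no scaling and 8 arrays as independent, gave 363 higher and 6029 lower genes, MYCN at -0.56 (adjusted p = 0.00245), immediate early genes at -0.13 (adjusted p = 3.09e-05), ribosomal genes at -0.16 (adjusted p = 0.117), MYCN-repressed genes at -0.019 (adjusted p = 0.0297), RPL19 at -0.012, and r = 0.999887 with the authors' deposited table. The median shift, spike-in scaling and no scaling moved the median of all genes to -0.23, -0.36 and -0.37, which shows why small positive values turned; camera compares a list with the other genes, so a turned median is no loss of a list's shift. After quantile normalization ribosomal genes lay at 0.022 and did not pass (adjusted p = 0.379). Over the scalings of the processed signal in the same fit MYCN's adjusted p ran from 0.0045 without scaling to 0.225.

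Without a filter 197 genes were higher and 6 lower, 24 named genes and 11 lists passed, and the median technical SD was 0.172; this setting tests more genes, including dim ones. All 8 arrays as independent gave 1695 lower genes, the RNA sample as a random block 1822 higher and 2001 lower, trend and robust settings 1876 lower, and the slide as a block 1790 lower. The random-block correlation was -0.12, and 0.12 with the slide as a block. Both of these fits thus counted technical arrays nearly as separate samples. The sample number as a block gave 1181 higher and 915 lower. The first technical arrays alone gave 703 higher and 494 lower genes, and the second alone 387 and 136, with 48 named genes passing against 80; fewer arrays carry more technical spread. Without the second array of the second MYCNcra sample 3 lists passed, with immediate early genes at 0.35 (adjusted p = 0.0662) and ribosomal genes at 0.11 (adjusted p = 0.135).

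With each RNA sample left out, where the lone sample is assumed to vary like the other group, higher genes ranged from 618 to 976 and lower genes from 316 to 763, with the fewest without either NC sample (666 and 316 without the first, 618 and 318 without the second) and 606 lower without the first MYCNcra sample. Lists passing ranged from 4 to 6, and named genes from 58 to 70. Medians ranged from 1.82 to 2.05 for p53 targets, -0.36 to -0.28 for MYC targets, -0.53 to -0.41 for mitotic genes, 0.13 to 0.28 for ribosomal genes and 0.11 to 0.51 for immediate early genes, which did not pass without the second MYCNcra sample (0.40, adjusted p = 0.0661) or the first NC sample (0.11, adjusted p = 0.119). MYCN ranged from -0.20 to -0.13. Where a cause is not named above, the cause was not tested. Signal over background limits the dim genes: folds are lower bounds where a whole group was dim, and fitted values where 1 to 3 of its arrays were above background.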

Other observations

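The genes and lists in this part were chosen after their values, or those of related genes, were seen. MYC, TERT and MIR17HG belong to lists of the report that did not pass camera's test and are given here as single values. MYC fell 1.65-fold, from a low level (log2 difference -0.73 ± 0.12 SE, n = 2 per group, limma adjusted p = 0.0146), and TERT, the catalytic subunit of telomerase, fell 2.01-fold (adjusted p = 0.00435). MIR17HG, the host transcript of a microRNA cluster known to be driven by MYC, fell 1.59-fold, whereas PVT1, the long non-coding RNA beside MYC, rose 1.81-fold. TP73, a transcription factor gene, rose 1.62-fold. TNFRSF10B, a member of the p53 list, rose 3.15-fold, and TNFRSF10D was at least 3.78-fold higher. Of the 87 genes that rose by 4-fold or more, with dim genes at their lower bound, 16 were on the p53 list. Of 209 small nucleolar and Cajal body RNAs tested, 11 rose and 22 fell, with a median of -0.03. These counts depended on the scaling: 8 rose and 25 fell after quantile normalization (median -0.06), 5 and 75 after a median shift (-0.26), and 1 and 27 with spike-in scaling (-0.39), where the last 2 moved the median of all genes to -0.23 and -0.36.

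The circadian clock genes PER2, CIART and HLF were among the clearest falls, with log2 differences of -1.23, -1.42 and -1.17, and prompted a look at other known targets of the clock. Of 8 measured ones, 5 fell and none rose: NR1D2 (-1.10), TEF (-0.98), CRY1 (-0.81), DBP (-0.60) and NR1D1 (-0.53), while PER1 (-0.39, adjusted p = 0.0506), BHLHE40 (-0.44, adjusted p = 0.255) and CRY2 (-0.09, adjusted p = 0.520) did not pass. Their median was -0.57 (camera p = 1.25e-05, and p = 0.0456 with an estimated correlation, neither adjusted for other lists), -0.65 after quantile normalization, and -0.79 and -0.92 under median and spike-in scaling. A bias with signal level is argued against, since the lowest of 10000 matched medians was -0.46. A different clock phase in the groups, for example from handling at different times, may account for the falls and cannot be excluded: the 3 measured genes of the opposite phase had a median of -0.019, with BMAL1 at 0.26 (adjusted p = 0.0761), NFIL3 at -0.11 and CLOCK at -0.02, and the times of handling are not given in the sources used here. An effect of the construct on the clock stays a hypothesis.

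Probes for ERCC control RNAs lay above background at 20 to 69 spots per array in no pattern with group: 69, 21, 37 and 23 spots on the MYCNcra arrays and 32, 45, 61 and 20 on the NC arrays.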
